A study of Homo sapiens with 12 samples.

How the data were processed

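RNA was measured by sequencing in JEG-3 cells, a cell line from a human choriocarcinoma, in which the YAP1 gene was targeted with CRISPR-Cas9. The labels give 12 libraries: 8 from knockout cells and 4 from wild-type cells. They come from 4 knockout lines (18, 27_5, 27_6 and 27_7) and 2 wild-type lines (27C1 and 27C2), with 2 libraries per line. The libraries of line 18 carry the titles 18_4 and 18_2. They were taken as 1 line, since the series text counts 4 knockout lines, and as separate lines in an alternative. The labels do not say whether the duplicates of a line were separate cultures. Per the labels' protocols, cells grew in DMEM with serum and puromycin, polyadenylated RNA was selected, and libraries were made with a strand-specific kit and read from 1 end on a NextSeq500.

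The deposited table holds raw read counts per gene symbol, whole numbers without normalization, with 1 column per library and 25536 genes. Per the submitters' processing notes, the tools were FastQC, HISAT2 2.1.0, SAMtools 0.1.18 and featureCounts 1.5.2, with the genome build GRCh38. The notes do not state the annotation, the strand setting or how reads with several matches were counted. Levels of overlapping, antisense and near-identical genes are therefore less certain than others. Each of the 12 columns was matched to its sample by name, and 0 columns were left over. Library totals ran from 17949957 to 28668927 counts. The reads carry no molecular identifiers, so precision from depth covers counting error only.

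Levels are CPM, counts scaled to library size after TMM normalization. The comparison of genotypes used counts summed over the libraries of each line, which gave 4 knockout and 2 wild-type sums. The line was taken as the independent unit of the knockout. Genes passed edgeR's filterByExpr by genotype, and 14102 were tested. The test was edgeR's quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest) with Benjamini-Hochberg adjustment. Every adjusted p for a gene, unless another tool is named, comes from edgeR, and an adjusted p under 0.05 counts as called. Log2 fold changes are knockout minus wild type, and their standard errors (SE) follow from the same fit. Error bars on line means are standard deviations (SD) over lines.

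Lines were compared in an edgeR fit of all 12 libraries with 1 mean per line (13647 genes tested). Each knockout line was set against the mean of both wild-type lines, the wild-type lines against each other, and the knockout lines were tested for equality with an F test. The p-values of these line comparisons measure only the spread between duplicates, which may be technical. The knockout comparisons share their controls. Their overlap was therefore set beside 20 simulations without a knockout effect, beside independent lists of the same sizes, and beside a version with 27C1 as control for 2 lines and 27C2 for the others. For YAP1, a two-sided exact permutation test of the 6 line means was added.

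In all, 24 gene lists were fixed, and 23 had a tested member. They were tested on voom values of the line sums with limma's camera, at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry. Fry's p tests whether the genes of a list move, on balance, in 1 direction and makes no comparison with other genes. List p-values were adjusted over the 23 lists. Members were counted as called over all genes tested and as adjusted over the list alone. Older gene symbols in the table were matched to current ones. Levels of markers of fibroblasts, endothelium, leukocytes, erythroid cells and pluripotent or yolk sac cells were checked as well.

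The genes named by rule were YAP1, then 15 fixed genes of the Hippo pathway, trophoblast and cell cycle. The rule added the 8 largest called rises and the 8 largest called falls with a mean log2 CPM of at least 3 and all knockout lines on the same side of both wild-type lines. It also added up to 3 called members per list by smallest p (2 members of smallest p where none was called). For the line comparisons it took the 4 largest called changes in each direction among genes with a mean log2 CPM of at least 3. Genes with clone-based names and pseudogenes were left out of both rankings. Where fewer than 3 genes were called in a direction, those of smallest p were named. Samples, tests, lists, the rule and most alternatives were fixed before the data were examined. Genes outside the rule are said to have been chosen after their values were seen, or are further members of a fixed list given as examples.

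Gene positions came from a RefSeq gene table for GRCh38. Of the gene names in the count table, 24749 matched it, as did 13778 of the tested genes. Call rates per chromosome were tested with Fisher's exact test against all other tested genes with a position, adjusted over the chromosomes. Medians along chromosomes used genes with a mean log2 CPM above 2. Transcript length and GC content came from the longest annotated transcript per symbol.

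Samples were also checked for structure other than genotype. Log2 CPM values (prior count 2) were used for principal components and for correlations between libraries. The library numbers in the labels divide the 12 libraries into a first and a second set of 6, each with 1 library per line. Within lines, 1269 of 13647 genes differed between the sets (edgeR). Differences that follow the title replicate numbers ran from r = -0.714 to r = 0.808 over 15 pairs of lines, so these numbers were not used for pairing. In the comparison of genotypes, 83 named genes were tested in both sets. Within-set values are given for the 12 of these whose log2 changes lay more than 1 apart, and for some others.

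The statistics were tested on simulated counts with known changes. In the comparison of line sums (13894 genes), 75% of genes changed by 1 on the log2 scale and 100% of genes changed by 2 were recovered, with 11 false calls (5.91% of calls). In a comparison of 1 line (13438 genes), 48% and 95% were recovered, with 13 false calls (8.33%). In the test of equality, 25% and 86% were recovered with 9 false calls (7.5%), and unchanged wild-type lines gave 0 calls. Of the simulated list changes, 100% were recovered with 0 false calls (13896 genes). Genes were simulated independently of one another. The list test was therefore not checked at the correlations estimated in the data, which reached 0.66 (pregnancy-specific glycoproteins).

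Alternatives covered the normalization (DESeq2 size factors, upper quartile), the filter, the test (DESeq2, limma voom, edgeR without robust estimation), the unit and blocks, the thresholds, thinning to the smallest total, and leaving out each line or library. In the comparison of genotypes, the set and replicate blocks took the 12 libraries as independent. The setting with correlated duplicates (limma) estimated a correlation within lines of -0.0835, so it hardly allowed for the pairing. Added later were genes off chromosomes 2 and 13, all libraries but 27_6 replicate 2, and each library set alone. Limma voom for the line comparisons was also added later. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Nothing in the count table was left out except genes removed by the filters.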

Results

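Gene expression was profiled in JEG-3 cells, a choriocarcinoma line that keeps properties of placental trophoblast, with and without the transcriptional coactivator YAP. YAP acts with TEAD transcription factors and is restrained by the Hippo kinases. The 4 knockout lines and 2 wild-type lines were each represented by 2 libraries of polyadenylated RNA. Total counts in replicates 1 and 2 were 20483170 and 17949957 for line 18, 21707077 and 23024221 for 27_5, 23516162 and 23643873 for 27_6, and 22651320 and 21632131 for 27_7. The wild-type libraries held 28668927 and 23043612 (27C1) and 27208715 and 21796946 (27C2). The 10 most abundant genes took 3.12% to 4.25% of a library.

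Libraries separated by genotype. The nearest library to each, by correlation over 10979 genes, had the same genotype in 12 of 12 cases but was its own duplicate in only 2. The median correlation was 0.972 within lines, 0.976 between lines of the same genotype and 0.951 between genotypes. Duplicates of a line always came from different library sets, whereas many pairs between lines shared a set. These medians and the nearest libraries are therefore not like for like. They do not show that duplicates are no closer than other lines. The first replicates of both wild-type lines were the closest pair (r = 0.997), with a chi-square of 3.09 per degree of freedom, above sampling noise. Library 27_6 replicate 2 lay apart on the second principal component. Its difference from its duplicate followed transcript length across genes (Spearman's rho = -0.508; genes are not independent replicates).

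**Figure D1:**
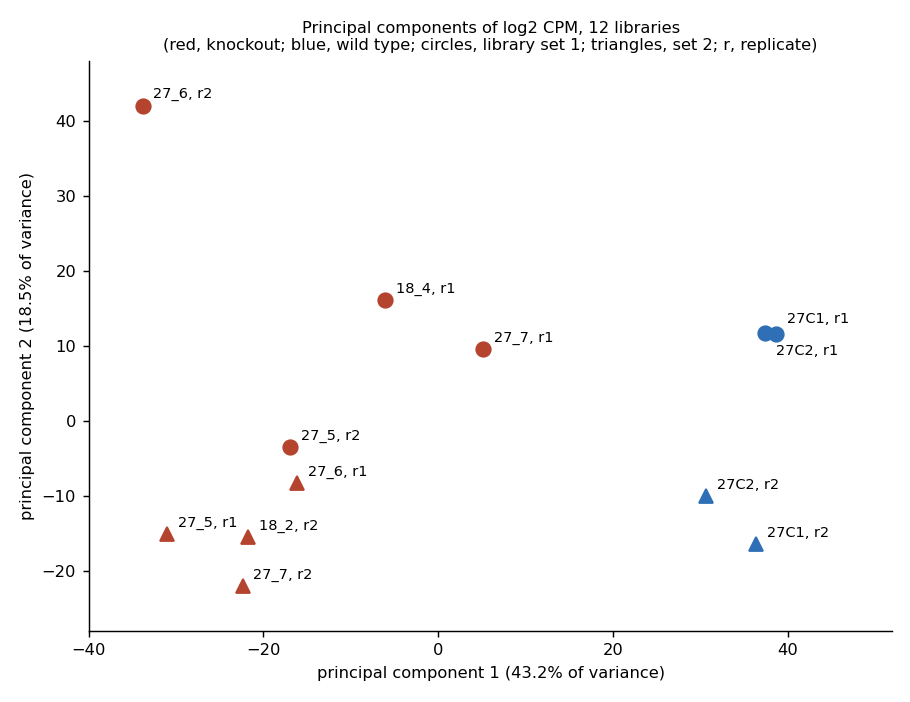
First and second principal components of log2 CPM (arbitrary units) for the 12 libraries, coloured by genotype, with symbols for the library sets. On the first component, the wild-type libraries sit between 30.71 and 38.66 and the knockout libraries between -33.84 and 5.096.

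YAP1 itself (chromosome 11, 102110447 to 102233424 on GRCh38) fell in every knockout line. Its level was 20.4 to 98.5 CPM in the 8 knockout libraries and 427 to 675 CPM in the 4 wild-type libraries. Line means were 44.67 ± 24.57 CPM (SD, n = 4) and 557.9 ± 4.765 CPM (SD, n = 2), so the knockout lines kept 8.01% of the wild-type level. The log2 change was -3.64 (SE 0.43, edgeR adjusted p = 0.00281), and -3.84 and -3.37 within the first and second library sets. The exact two-sided permutation test of the 6 line means gave p = 0.0667, the smallest value its 15 splits allow. Against the wild-type lines, single lines gave -3.66 (18), -4.47 (27_5), -4.19 (27_6) and -2.79 (27_7). The labels and this gene therefore go together in all 12 libraries.

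**Figure D2:**
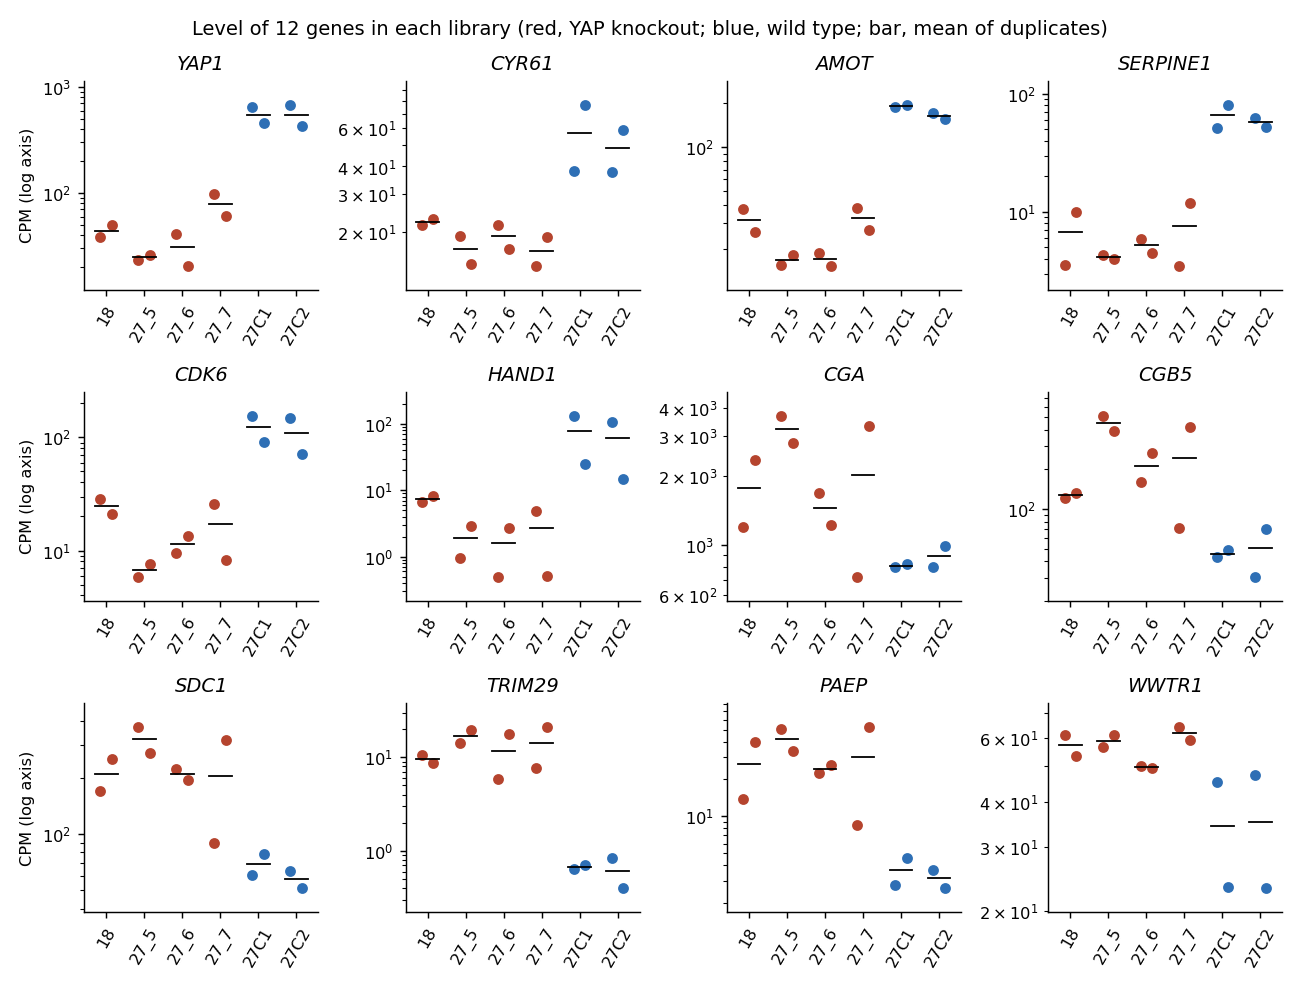
Level in CPM (log axis) of 12 genes in each library, by line, with knockout libraries in red, wild-type libraries in blue and bars at the mean of duplicates. YAP1 lies between 20.4 and 98.5 CPM in the knockout libraries and between 427 and 675 CPM in the wild-type libraries.

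The comparison of knockout with wild-type lines asks which genes differ between them. A background shared by the knockout lines would appear in it too, and no value here separates it from the loss of YAP. In the knockout lines, 1388 genes rose and 1137 fell of 14102 tested. Of 17 YAP/TAZ target genes 10 fell, 1 rose and 6 did not pass, and of 23 Hippo pathway and TEAD genes 13 fell, 2 rose and 8 did not pass (adjusted p = 0.42 with an estimated correlation for each list). MYOF, AMOT and CYR61 were among those that fell. Of 29 syncytiotrophoblast markers 14 rose, 2 fell and 13 did not pass (adjusted p = 0.42 with an estimated correlation). CGA and CGB5, subunit genes of chorionic gonadotropin, were among those that rose, but did not pass in the first library set alone (adjusted p = 0.379 and 0.106) or without a filter (0.0729 and 0.0846), nor did CGB5 in the second set alone (0.0683). Of 17 markers of cytotrophoblast and trophoblast stem cells 9 fell, 0 rose and 8 did not pass (adjusted p = 0.223 with an estimated correlation). CDK6, a G1 kinase, fell 7.98-fold, whereas 36 of 41 S phase genes and 50 of 55 G2/M genes did not pass the test. Genes of chromosome 2 shifted upwards together (median log2 change 0.33), those of proximal chromosome 13 downwards (-0.38) and those of distal chromosome 13 upwards (0.54). Named genes there are given with their chromosome.

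By edgeR's adjusted p, 2525 genes (17.9%) were called and 11577 were not. At an unadjusted p under 0.05 there were 4648. Of the called genes, 591 rose and 435 fell by at least 1 on the log2 scale. In 2525 of the 2525, the 4 knockout lines lay on the same side of both wild-type lines. Selection by the same comparison makes this nearly certain. Among all tested genes, the share was 48.1%. Chance gives 13.3% only if all lines vary alike and independently of one another. The wild-type lines were nearly alike (r = 0.9974 and 0.9928 within the library sets), so 13.3% cannot serve as a reference for the 48.1%. This likeness limits the test of genotypes as well. If the wild-type lines are not independent, its adjusted p-values and the wild-type SDs may understate the spread between control lines. The median log2 change of all genes was 0.02. The count rests on having both wild-type lines: it was 375 without 27C1 and 495 without 27C2. With 18_4 and 18_2 as separate lines it was 1612, and 14 named genes lost the call, among them ERVW-1 (adjusted p = 0.0548), DPPA3 (0.0693), TP63 (0.0755) and ASCL2 (0.13). Without a filter CGA, CGB5, ADA (adjusted p = 0.0934), THSD7A (0.084) and DPPA3 (0.0532) lost the call. The first library set alone called 350 genes and the second 2182. Of the 12961 genes tested in both sets, 268 were called in both, all in the same direction, and 2398 of 2406 pooled calls kept their sign in both. Of the 79 called named genes, 76 were tested in the first set alone and 52 of these did not pass there, among them WWTR1, TEAD4, CGA, CGB5, SDC1, ERVFRD-1 and ERVW-1. In the second set 8 of 78 did not pass, among them CGB5, HAND1, DPPA3 and PLAC8. Without 27C1 and without 27C2, 54 and 47 lost the call.

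The largest rises among well expressed genes included TRIM29, a TRIM family protein of stratified epithelia, from 0.654 ± 0.0311 CPM (SD, n = 2) to 13.1 ± 3.18 CPM (SD, n = 4). Its log2 change was 4.32 (SE 0.30, adjusted p = 0.000156). NRARP, a Notch target and feedback inhibitor, rose by 3.94 (SE 0.52, adjusted p = 0.00235; 3.33 and 4.40 within the sets) and PAEP, which encodes glycodelin, by 3.16 (SE 0.26, adjusted p = 0.000267). The secreted protein gene OAF (3.70), PLXDC2 (3.11), adenosine deaminase ADA (3.07) and the CD47 receptor SIRPA (2.94) rose as well. EGFR-AS1, antisense to EGFR, had the largest rise (4.64, SE 0.48, adjusted p = 0.000834; 4.08 and 5.23 within the sets). The strand setting is not stated, so its reads cannot be told from those of EGFR.

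The largest falls included HAND1, a transcription factor of trophoblast giant cells in the mouse. It went from 72.7 ± 11.8 CPM (SD, n = 2) to 3.38 ± 2.65 CPM (SD, n = 4), a log2 change of -4.45 (SE 0.55, adjusted p = 0.00368). Within the library sets it changed by -4.79 and -3.04. SLC4A8, a sodium-dependent bicarbonate exchanger, fell from 45.1 to 2.16 CPM (log2 -4.38, SE 0.19, adjusted p = 8.65e-06). SERPINE1, the plasminogen activator inhibitor PAI-1, fell from 61.1 to 5.90 CPM (log2 -3.37, SE 0.20, adjusted p = 0.000142). THSD7A (-3.74), DPPA3, known from oocytes and germ cells (-3.48; -5.19 and -2.59 within the sets), TBC1D9 (-3.26) and CDK6 (-3.00) completed the group with YAP1. CDK6 changed by -3.01 and -2.91 within the sets.

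Of 17 tested YAP/TAZ target genes, 10 fell, 1 rose and 6 did not pass; adjusted over the list alone, 11 fell and 2 rose. Their median log2 change was -0.89 (camera adjusted p = 0.000103; adjusted p = 0.42 with an estimated correlation; fry adjusted p = 0.0111). MYOF, a membrane repair protein, fell from 348 to 78.2 CPM (log2 -2.15) and ARHGEF17 fell by 1.11 on the log2 scale. The matricellular gene CYR61, now CCN1, fell from 51.7 to 18.6 CPM (log2 -1.48, SE 0.14, adjusted p = 0.000428; -1.20 and -1.74 within the sets). ANKRD1 fell by 2.25 at levels under 1 CPM. CTGF (CCN2) did not pass (log2 -0.89, adjusted p = 0.0566), with 2.00 against 3.70 CPM. On line sums it was called as lower by DESeq2 (adjusted p = 0.0275), by limma voom (0.037) and without line 27_7 (0.02). It was also called with the library set as a block (0.0283), which took the 12 libraries as independent. So it was with correlated duplicates in limma (0.0309), where the estimated correlation was -0.0835. GADD45B, a stress-response gene, was the member that rose (1.00). Library 27_6 replicate 2 had the lowest mean of these genes (-0.67 on the log2 scale against the mean of all libraries).

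Of 23 Hippo pathway and TEAD genes, 13 fell, 2 rose and 8 did not pass; adjusted over the list alone, 14 fell and 2 rose. The median was -0.49 (camera adjusted p = 9.37e-05; adjusted p = 0.42 with an estimated correlation; fry adjusted p = 0.0322). AMOT, which encodes the YAP-binding protein angiomotin, fell from 176 to 24.6 CPM (log2 -2.84, SE 0.28, adjusted p = 0.000736). The phosphatase gene PTPN14 (-1.03) and the kinase gene LATS2 (-1.57, on proximal chromosome 13) fell too. TEAD4 fell by 0.79 (adjusted p = 0.0165) and TEAD1 did not pass (-0.21, adjusted p = 0.301). WWTR1, which encodes the YAP paralog TAZ, rose from 35.7 to 56.9 CPM (log2 0.67, SE 0.12, adjusted p = 0.00571), with 0.34 in the first library set and 1.22 in the second. Here too, library 27_6 replicate 2 had the lowest mean (-0.57).

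Syncytiotrophoblast, the fused hormone-secreting layer of the placenta, was represented by 29 tested markers. Of these 14 rose, 2 fell and 13 did not pass; adjusted over the list alone, 19 rose and 2 fell. The median was 0.99 (camera adjusted p = 1.31e-05; adjusted p = 0.42 with an estimated correlation; fry adjusted p = 0.0531). CGA, the common alpha subunit of glycoprotein hormones, rose from 845 to 2112 CPM (log2 1.32, SE 0.30, adjusted p = 0.0201; 0.89 and 1.59 within the sets). CGB5, a beta subunit gene of chorionic gonadotropin, rose from 47.3 to 257 CPM (log2 2.44, SE 0.51, adjusted p = 0.0203; 2.53 and 2.32 within the sets). Reads can match several CGB copies, so the value of each copy is less certain. The fusion gene ERVFRD-1 (syncytin-2) rose from 171 to 405 CPM (log2 1.24; 0.68 and 1.65 within the sets) and ERVW-1 (syncytin-1) from 51.0 to 112 CPM (1.14). ENDOU (2.04) and SDC1 (1.90, on chromosome 2) also rose, and LGALS13 (-3.40) and HSD17B1 (-0.53) fell. GCM1, a transcription factor upstream of the syncytins, did not pass (0.14, adjusted p = 0.443). Library 27_7 replicate 1 had the lowest mean of the list among all 12 libraries (-0.75). Of the pregnancy-specific glycoproteins, 5 were tested: 2 fell, 0 rose and 3 did not pass; adjusted over the list alone, 4 fell. Their median was -2.68 (camera adjusted p = 0.00056; adjusted p = 0.42 with an estimated correlation; fry adjusted p = 0.0327). PSG3 went from 1.20 to 0.0744 CPM (log2 -7.31 and -3.42 within the sets) and PSG4 from 0.753 to 0.0396 CPM, with counts for PSG4 in only 1 of the 8 knockout libraries. DESeq2 did not call PSG4 (adjusted p = 0.261). These genes are near-identical copies, so their reads are uncertain.

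Of 17 tested markers of cytotrophoblast and trophoblast stem cells, the proliferating precursor cells, 9 fell, 0 rose and 8 did not pass; adjusted over the list alone, 13 fell and 1 rose. The median was -0.52 (camera adjusted p = 9.37e-05; adjusted p = 0.223 with an estimated correlation; fry adjusted p = 0.0012). The list's estimated correlation was -0.0362, under the preset 0.01, so correlation between its genes cannot account for the lost call. TP63, a transcription factor of epithelial stem cells, fell from 25.3 to 6.70 CPM (log2 -1.92, SE 0.28, adjusted p = 0.00323; -3.02 and -1.47 within the sets). CDX2 fell from 7.43 to 1.82 CPM (log2 -2.03, on proximal chromosome 13; -1.41 and -2.95 within the sets), and PAGE4 from 1.98 to 0.221 CPM (-2.27 and -3.59 within the sets). ELF5 did not pass (0.72, adjusted p = 0.203), with 1.36 and -0.10 within the sets. Extravillous trophoblast markers, of the invasive cells, gave 3 rises, 5 falls and 9 that did not pass of 17 (adjusted over the list alone, 5 rose and 5 fell). Their median was 0.36, while camera and fry pointed downwards (adjusted p = 0.935 and 0.302). SERPINE1 is a member that fell, as did PLAC8 (-1.25; -2.43 in the first library set and 0.24 in the second), and FSTL3 rose (0.91; 0.40 and 2.29 within the sets).

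**Figure D3:**
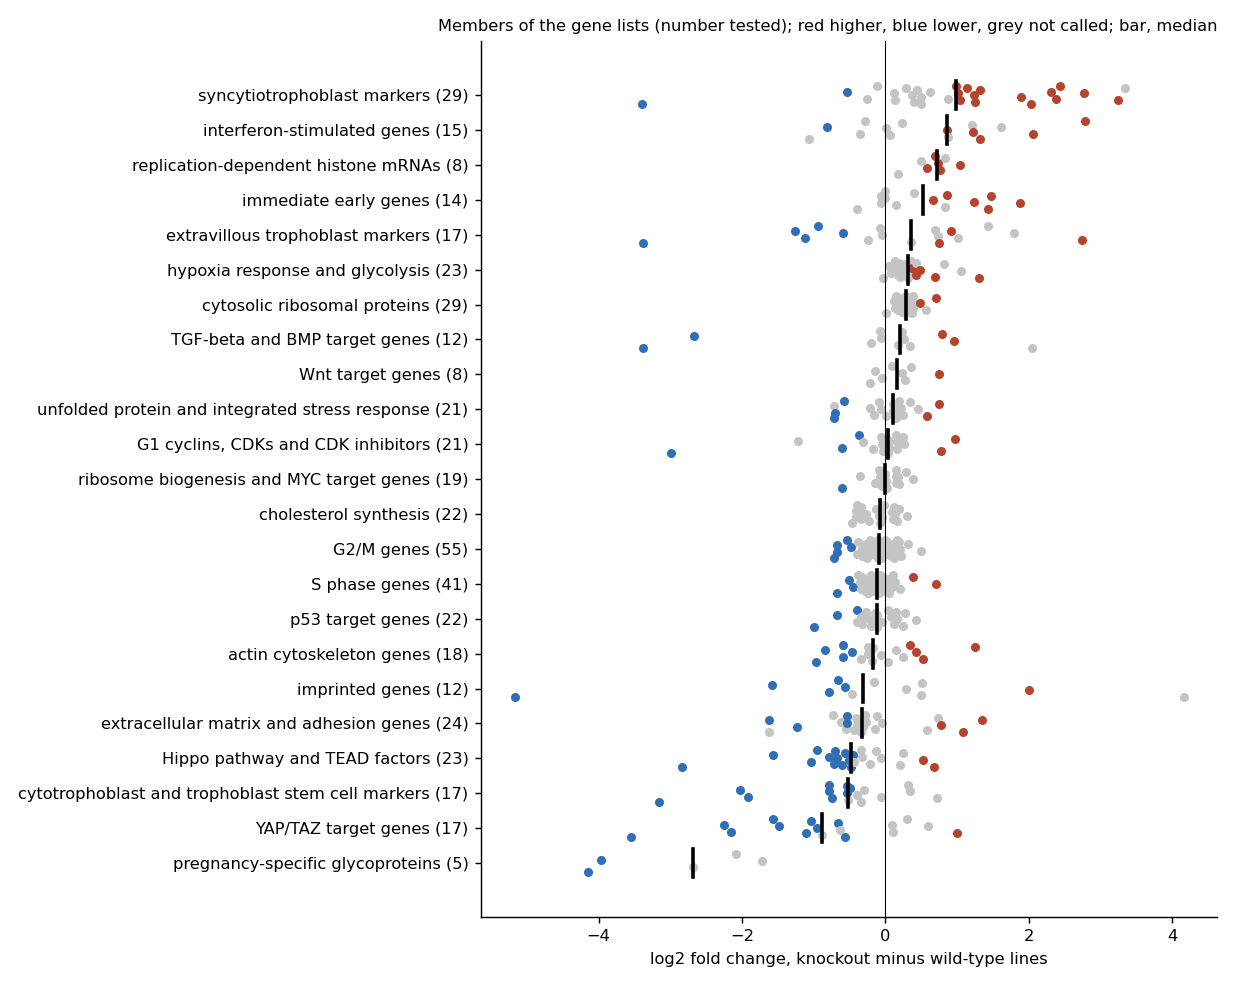
Log2 fold change (knockout minus wild-type lines) of the tested members of 23 gene lists, with called members coloured and a bar at each list's median. Medians run from -2.68 for the pregnancy-specific glycoproteins to 0.99 for the syncytiotrophoblast markers.

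Cell cycle genes were tested in 3 lists. Of 41 S phase genes, 2 rose, 3 fell and 36 did not pass (1 rose and 3 fell adjusted over the list alone), with a median of -0.12. Camera called the list lower (adjusted p = 0.0249; adjusted p = 0.608 with an estimated correlation; fry adjusted p = 0.115). The call was also lost in the first library set alone (0.256), without 27_5 (0.0877), without 27C2 (0.0911) and with correlated duplicates (0.0662). RRM2, a ribonucleotide reductase subunit, rose by 0.71 and lies on chromosome 2, and BRIP1 (-0.68) and UHRF1 (-0.50) fell. Of 55 G2/M genes, 5 fell and 50 did not pass (2 fell adjusted over the list alone; median -0.09, camera adjusted p = 0.0577). KIF23 fell by 0.72, CBX5 by 0.68 and CKAP2, on proximal chromosome 13, by 0.67. Cyclin A2 (CCNA2) did not pass (-0.21, adjusted p = 0.301). Of 21 G1 regulators, 2 rose, 3 fell and 16 did not pass, with the same counts adjusted over the list alone. Their median was 0.04 and their mean -0.14 (camera downwards, adjusted p = 0.731). CDK6 fell from 119 to 14.9 CPM (log2 -3.00, SE 0.43, adjusted p = 0.00591), RB1 (-0.61, on proximal chromosome 13) fell, and CDKN2A rose by 0.98. p53 target genes gave 0 rises, 3 falls and 19 that did not pass of 22 (3 fell adjusted over the list alone; median -0.12, camera adjusted p = 0.076). The falls were ZMAT3 (-0.99), RRM2B (-0.67) and TNFRSF10B (-0.39). TNFRSF10B passed in neither library set alone (edgeR adjusted p = 0.172 and 0.0561). Nor did CDKN2A (0.055 and 0.206) or BRIP1 (0.167 and 0.0685).

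Of 14 immediate early genes, 6 rose and 8 did not pass, with 6 adjusted over the list alone. The median was 0.53 (camera adjusted p = 0.00985; adjusted p = 0.42 with an estimated correlation; fry adjusted p = 0.0299). FOSB rose by 1.47, IER3 by 1.24 and IER2 by 0.86, but none of these passed in the first library set alone (edgeR adjusted p = 0.165, 0.489 and 0.177). Of 23 hypoxia and glycolysis genes, 5 rose and 18 did not pass (7 rose adjusted over the list alone). The median was 0.31 (camera adjusted p = 0.000243; adjusted p = 0.463 with an estimated correlation; fry adjusted p = 0.0747). ADM, the peptide adrenomedullin, rose from 47.9 to 119 CPM (log2 1.31), GPI rose by 0.42, and KDM3A, on chromosome 2, by 0.69. The first library set alone did not call either list (camera adjusted p = 0.256 for both, against 0.00985 and 0.000243 pooled). Means of the hypoxia list were lowest in replicate 2 of 27C1 and of 27C2 (-0.567 each, log2 scale). Replicate 1 of 27C1 (0.0314) and of 27C2 (0.045) lay within the knockout range of -0.0711 to 0.352. Of 15 interferon-stimulated genes, 5 rose, 1 fell and 9 did not pass (5 rose and 2 fell adjusted over the list alone; median 0.86, camera adjusted p = 0.193). ISG15 rose by 1.23 and BST2 by 2.06, and HERC5 fell by 0.81.

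Extracellular matrix and adhesion genes went both ways. Of 24, 3 rose, 4 fell and 17 did not pass (3 rose and 6 fell adjusted over the list alone). The median was -0.33 (camera adjusted p = 0.0131; adjusted p = 0.608 with an estimated correlation, 0.192 in the first library set and 0.123 with correlated duplicates; fry adjusted p = 0.168). The fibril-associated collagen gene COL12A1 fell by 1.23, while the basement membrane collagens COL4A1 (1.08) and COL4A2 (0.78), both on distal chromosome 13, rose. Library 27_6 replicate 2 had the lowest mean of this list (-0.64). Of 18 actin cytoskeleton genes, 4 rose, 5 fell and 9 did not pass (4 rose and 6 fell adjusted over the list alone; median -0.18, camera adjusted p = 0.329). The calponins CNN2 (-0.96) and CNN3 (-0.85) fell and the tropomyosin TPM2 rose (1.25). TGF-beta and BMP targets gave 2 rises, 2 falls and 8 that did not pass of 12, with the same counts adjusted over the list alone. Their median was 0.21 and their mean -0.13, with camera pointing up and fry down (adjusted p = 0.935 and 0.128). ID3 rose by 0.96, and TGFBI fell with levels under 1 CPM in both groups (not called by DESeq2, adjusted p = 0.0602). Of 8 Wnt targets, 1 rose and 7 did not pass (1 adjusted over the list alone; median 0.17, camera adjusted p = 0.337). That was ASCL2 (0.75), a trophoblast transcription factor.

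Imprinted genes, expressed from 1 parental copy, gave 1 rise, 5 falls and 6 that did not pass of 12, with the same counts adjusted over the list alone. The median was -0.31 (camera adjusted p = 0.144; fry adjusted p = 0.0125). SNRPN, in the imprinted region of chromosome 15 (24823637 to 24978723), fell from 10.5 to 0.282 CPM (log2 -5.17, SE 0.43, adjusted p = 0.000322; -4.77 and -5.87 within the sets). SGCE (-0.66) and GRB10 (-0.56) fell as well. IGF2 fell from 3817 to 1278 CPM (-1.58, SE 0.33, adjusted p = 0.0190), and PHLDA2, a growth-restraining placental gene, rose by 2.00. Single libraries of IGF2 overlapped, with 320 to 2470 CPM in knockout and 1960 to 5610 CPM in wild type. H19 did not pass (4.17, SE 1.55, edgeR adjusted p = 0.130). Of 8 tested histone mRNAs, from a list of replication-dependent histones that also holds H1F0, 5 rose and 3 did not pass (6 rose adjusted over the list alone). The median was 0.72 (camera adjusted p = 0.000243; adjusted p = 0.42 with an estimated correlation; fry adjusted p = 0.0125). HIST1H4H rose by 1.05, HIST1H2BK by 0.77 and HIST1H2BC by 0.74. Poly(A) selection captures the polyadenylated part of these mRNAs. Of 29 cytosolic ribosomal proteins, 2 rose and 27 did not pass, with 2 adjusted over the list alone. The median was 0.29 (camera adjusted p = 1.31e-05; adjusted p = 0.607 with an estimated correlation; fry adjusted p = 0.113). RPS18 rose by 0.48 and RPS27A, on chromosome 2, by 0.70. Library 27_6 replicate 2, with its trend against long transcripts, had the highest mean of both lists (0.47 and 0.62).

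Camera called none of 3 further lists. Of 21 genes of the unfolded protein and integrated stress response, 2 rose, 3 fell and 16 did not pass, with the same counts adjusted over the list alone (median 0.11, camera adjusted p = 0.618). TRIB3 (-0.70) and SLC7A11 (-0.72) fell, and PHGDH, of serine synthesis, rose (0.59). SLC7A11 passed in neither library set alone (edgeR adjusted p = 0.0778 and 0.0873). Of 19 ribosome biogenesis and MYC targets, NOP16 fell (-0.60) and 18 did not pass, with 0 adjusted over the list alone. Their median was -0.01 and their mean 0.00 (camera adjusted p = 0.935). Among 22 cholesterol synthesis genes, 0 passed by edgeR over all genes and 0 adjusted over the list alone (median -0.08, camera adjusted p = 0.162). DHCR24 (-0.40, adjusted p = 0.0543) and FDFT1 (-0.41, adjusted p = 0.0628) had the smallest p. Both were called as lower by DESeq2 on line sums (adjusted p = 0.0202 and 0.0278) and in some other alternatives. They were also called with the set as a block (edgeR adjusted p = 0.0226 and 0.0349) and with the replicate block (0.0298 and 0.0455). These blocks took the 12 libraries, not the lines, as independent units. The count table held 0 of 13 mitochondrially encoded mRNAs. Over the 23 lists, camera called 5 higher and 6 lower, 0 held with an estimated correlation, and fry called 7.

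Fold changes by position were compared to see whether changes cluster on chromosomes. On chromosome 2, 302 genes rose and 34 fell of 904 tested (37.2% called, Fisher's exact adjusted p = 1.25e-43). On chromosome 13, 46 rose and 60 fell of 250 (42.4%, adjusted p = 2.31e-18). Chromosomes 8 (10.7%), 10 (13.5%) and 22 (10.6%) held fewer called genes than the rest (Fisher's exact adjusted p = 0.000106, 0.015 and 0.00084). That rest includes chromosomes 2 and 13, which raise its rate, and no test without them was run. Chromosome 2 held 21.8% of all rises and 6.41% of tested genes. Of 678 better expressed genes there, 83% had a fold change above 0, and the median log2 change was 0.30 (line 18), 0.32 (27_5), 0.28 (27_6) and 0.35 (27_7). The 114 proximal genes of chromosome 13 (19633659 to 60573879) had a median of -0.38 and the 68 distal genes (72708367 to 114327322) one of 0.54. The boundary between these regions, at 66 Mb, was not fixed beforehand, so their opposite medians are no test of that division. Medians of the other chromosomes lay between -0.09 and 0.09. Away from chromosomes 2 and 13, 1040 genes rose and 1043 fell.

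**Figure D4:**
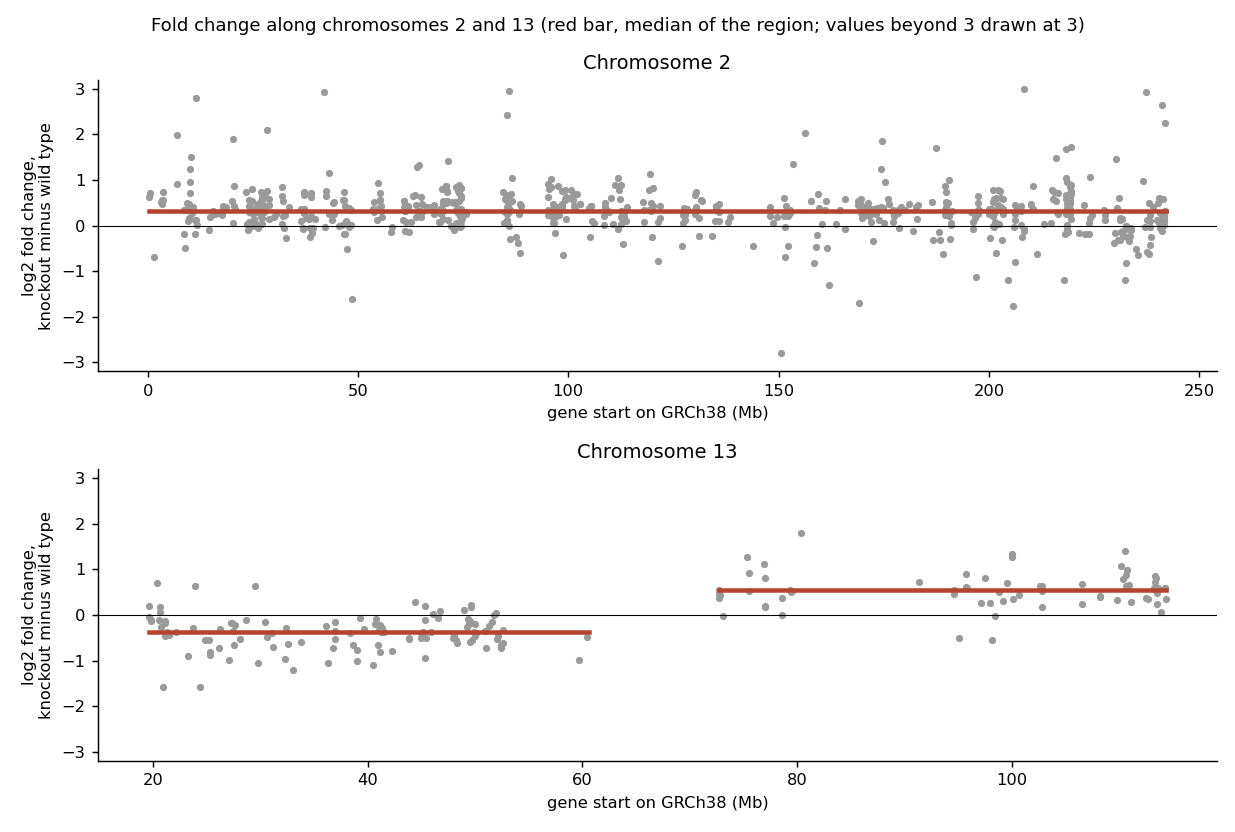
Log2 fold change (knockout minus wild-type lines) of each gene with a mean log2 CPM above 2 against its start in Mb, with bars at the region medians. Medians are 0.33 on chromosome 2, -0.38 on proximal and 0.54 on distal chromosome 13, divided at 66 Mb.

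Each knockout line was then set against the wild-type lines to see which changes recur. Ranks are among genes with a mean log2 CPM of at least 3, so larger changes of genes with lower levels, such as PTH2R, SBSN, SLPI and PCDH17 (chosen after their values were seen), stand outside them. TRIM29 was among the 4 largest called rises in each of the 4 lines (log2 3.87 in 18, 4.68 in 27_5, 4.13 in 27_6 and 4.44 in 27_7). EGFR-AS1 was among them in 27_5 (5.25), 27_6 (4.36) and 27_7 (4.80). OAF was among them in 18 (3.93) and 27_5 (4.29), and H19, an imprinted non-coding RNA, in 18 (6.31) and 27_6 (4.27). The melanoma antigen gene MAGEB2 rose in 27_6 (5.52) and 27_7 (5.43), NRARP in 18 (4.84), ADA in 27_5 (3.78) and COL6A3, on chromosome 2, in 27_7 (3.59). Among the 4 largest called falls of such genes in each line, the annexin ANXA3 stood in 18 (-8.77), 27_5 (-11.3) and 27_6 (-7.39). In 27_5 its level was 0 and 0.0444 CPM, against 64.3 to 79.7 CPM in wild-type libraries. HAND1 (-5.14 and -5.44) and the surface glycoprotein TACSTD2 (-5.85 and -6.07) were in 27_5 and 27_6. THSD7A was in 18 (-6.34) and 27_7 (-3.55). DPPA3 (-5.12, 27_5), TBC1D9 (-4.72, 27_6), MAGEB16 (-5.86, 18), APBB1IP (-4.76, 18), SLC4A8 (-4.08, 27_7), FSTL5 (-3.57, 27_7) and ALPK3 (-3.22, 27_7) completed these falls.

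Of 13647 genes tested by edgeR, line 18 had 282 rises and 226 falls, 27_5 758 and 478, 27_6 671 and 690, and 27_7 280 and 194. In all 4 lines, 137 genes rose and 108 fell. This fit leaves out the library set, although 1269 genes differed between the sets within lines. With the set as a block, 1277 (18), 2052 (27_5), 2778 (27_6) and 961 (27_7) genes were called, and 526 in all 4 lines. With 18_4 and 18_2 as separate lines, 45 genes were called in all lines. Simulations without a knockout effect gave 0 and 0, independent lists 0.016 and 0.0057, and separate controls 26 and 44. The mean correlation of fold changes between lines was 0.801 over 9224 genes, against 0.33 in those simulations and 0.798 with separate controls. The wild-type lines were nearly alike (r = 0.9974 and 0.9928 within the library sets), so such controls are hardly separate. The simulations hold no background shared by the knockout lines. Neither comparison can therefore tell a recurring effect of YAP loss from such a background. Leaving out 1 library at a time gave 97 genes (without 18_2 replicate 2) to 800 (without 27_6 replicate 1) for line 18 and 187 (without 27_5 replicate 1) to 1502 for 27_5. It gave 156 (without 27_6 replicate 2) to 3642 (without 27_6 replicate 1) for 27_6 and 28 (without 27_7 replicate 2) to 591 for 27_7. The count in all 4 lines went from 26 (without 27_7 replicate 2) to 283, and every left-out library except 27_6 replicate 1 (283) and 27_7 replicate 1 (234) took it to between 26 and 141. Without single wild-type libraries, counts were 190 to 268 (18), 712 to 885 (27_5), 580 to 742 (27_6) and 167 to 283 (27_7). Without 27_5 replicate 1 or 2 they were 259 and 278 (18), 812 and 851 (27_6) and 272 and 289 (27_7). Line 18 also gave 191 without 18_4 replicate 1 and 771 without 27_6 replicate 2, and 27_5 gave 390 without its replicate 2.

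Differences between the knockout lines were tested gene by gene for equality of the 4 lines. This test recovered only 25% of simulated changes of 1 on the log2 scale, so a gene that did not pass may still differ. ZNF512, a zinc finger gene on chromosome 2, stood at 18.0 and 16.4 CPM in line 27_6 and at 0.189 to 0.462 CPM in the other 10 libraries. ANXA3 stood at 45.2 and 26.6 CPM in line 27_7 and at 0 to 0.696 CPM in the other knockout lines. Both had an edgeR adjusted p of 0.000264 for equality of the 4 lines, and CA12, a carbonic anhydrase, did not pass (adjusted p = 0.0754). These were the 2 genes called of 13647, with 860 at an unadjusted p under 0.05. DESeq2 called 131, limma voom 1, and edgeR without 27_6 replicate 1 called 103. Leaving out 18_2 replicate 2 gave 6, and 27_5 replicate 2 or 27_7 replicate 1 gave 4 each.

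The wild-type lines 27C1 and 27C2 served as background for differences between unedited lines. No gene was told apart between them at this depth and replication: edgeR called 0 of 13647, with 26 at an unadjusted p under 0.05. DESeq2 called 0 (16 unadjusted), limma voom 0 (22 unadjusted) and edgeR with the set as a block 0 (54 unadjusted). Without that block, the spread between duplicates includes the difference between library sets. Within a set these lines correlated at 0.9974 (first) and 0.9928 (second), against 0.9767 (27C1) and 0.9787 (27C2) between their own duplicates. They were nearly alike, so 0 calls is a weak measure of how far independent lines differ. The genes of smallest p, none of which passed, were BOLA2B (log2 -6.04, SE 1.12, edgeR adjusted p = 1), RPL13AP3 (-3.34) and FGF13 (-3.13) on the lower side in 27C1. SYT16 (1.75), DAGLA (1.52) and NPIPB8 were on the higher side. BOLA2B and NPIPB8 belong to families of near-identical copies.

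Markers of other cell types were checked as levels. All 6 erythroid markers stayed under 1 CPM in every library, as did 5 of 7 leukocyte, 4 of 10 fibroblast, 2 of 6 endothelial and 4 of 7 pluripotent or yolk sac markers. PTPRC, TYROBP, DCN, THY1 and POSTN had 0 counts in the 12 libraries. Markers present in both genotypes included CDH5 (174 CPM in knockout and 99.6 CPM in wild-type libraries), CSF1R (64.1 and 85.0 CPM) and COL6A3 (69.7 and 8.58 CPM), none of which passed (adjusted p = 0.271, 0.158 and 0.0972). COL1A1 (log2 -0.54) and PDGFRB (-1.97) fell, as did LIN28B (-0.67), an RNA-binding protein of early development, and the transcription factor gene SALL4 (-0.60). Among markers with group means under 1 CPM, COL1A2 (-2.44) and COL3A1 (-2.05) fell and SOX2 (3.45, adjusted p = 0.0279) and VWF (1.38, adjusted p = 0.0478) rose.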

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

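Tests of single genes on chromosome 2, of chromosome 13, of transcript length, of GC content and of the 15q11 region were chosen after the results were seen; the other tests were set before their results were seen. Groups are the 8 knockout and the 4 wild-type libraries. In 172 groups of values of named genes, 8 had a library far from the others. Chance flags about 1 in 20 groups, which gives 8.6 here. For each, the gap to the nearest library is given as a share of the group's range.

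TEAD1 was lowest in 27_6 replicate 2 among the knockout libraries (gap 0.667). CGA was highest (0.877) and ERVFRD-1 lowest (0.842) in 27C2 replicate 2 among the wild-type libraries. NRARP was highest in 18_2 replicate 2 (0.619). PSG3 was highest in 27C1 replicate 2 among the wild-type libraries (0.939), and PSG4 was counted in 27_7 replicate 2 alone among the knockout libraries (gap 1). FDFT1 was highest in 27_7 replicate 2 (0.551) and ASCL2 in 18_4 replicate 1 (0.618). Knockout lines differed in ZNF512 (adjusted p = 0.000264 in edgeR's F test of equality), high in line 27_6 alone, and in ANXA3 (adjusted p = 0.000264), which stood at 45.2 and 26.6 CPM in line 27_7, under the 64.3 to 79.7 CPM of the wild-type libraries, and at 0 to 0.696 CPM in the other knockout lines.

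Genes of chromosomes 2 and 13 shifted together in all 4 knockout lines. A bias by GC content and transcript length is argued against, since the shift of chromosome 2 against the other chromosomes was 0.35 before and 0.377 after a smooth fit on both was removed; chromosome 13 kept -0.35 (proximal) and 0.60 (distal). Separate changes of many single genes stay open: the 25th percentile on chromosome 2 lay 0.31 above that of the other chromosomes, which follows from the share of its genes above 0 (83%) and decides nothing. A difference in copy number predicts a shift at every expression level. Over 3 equal groups of genes by expression, the smallest shift of chromosome 2 was 0.34, and shifts were -0.41 to -0.30 on proximal and 0.45 to 0.62 on distal chromosome 13. Copy numbers that differ between the knockout and the wild-type lines are therefore a candidate explanation, which has not been tested on DNA. The 4 knockout lines share the shift, so they may descend from cells that differed from the wild-type lines in more than YAP, and no value here separates an effect of such a background from that of the knockout.

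Library 27_6 replicate 2 lay apart from the other libraries. Contamination with RNA from cells of another type is argued against: of 12713 genes under 1 CPM in every other library, 0 reached 10 CPM in it, and the highest stood at 2.78 CPM. Its difference from its duplicate fell with transcript length (Spearman's rho = -0.508 across genes, against -0.0565 to 0.315 in the other lines), with medians of 0.44 in the shortest 10% and -0.52 in the longest 10% of transcripts. It also followed GC content at fixed length (partial rho = 0.485, against -0.332 to -0.0827). A loss of long transcripts and a GC bias both remain open, and no biological explanation was tested.

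SNRPN and the transcripts downstream of it were near 0 in the knockout lines. All 10 tested genes from SNRPN to IPW fell, IPW from 4.56 to 0.0158 CPM, while MKRN3 (log2 -0.08, SE 0.14) and UBE3A (-0.10, SE 0.09) on either side did not pass. A lower copy number of the surrounding region is argued against by the median of the other 12 tested genes within 3 Mb (-0.111). Even so, 4 of them were called: REREP3 (-1.99), NIPA1 (-1.05) and HERC2 (-0.70) as lower and OCA2 (2.90) as higher. Reads shared between SNORD116 copies cannot account for SNRPN itself, outside these copies, at -5.17. For the copies they stay open, since all 6 tested copies fell together and SNRPN fell as well. Silencing of the transcript that runs through the region, or a small deletion, may apply, and counts alone cannot separate them, nor say whether it came with the knockout or with the cells' background.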

How the results depend on the processing

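The alternatives without chromosomes 2 and 13, without 27_6 replicate 2, with each library set alone, and limma voom for the line comparisons were chosen after the data were seen; all others were fixed before. Counts are called genes.

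The count between genotypes (2525) stayed within 1.5 times under both other normalizations (2482 and 2568), no filter (2373), no robust estimation (2478), DESeq2 (3153), limma voom (2547), 12 independent libraries (2618), the replicate block (2655), the set block (3275), correlated duplicates (2997), thinning (2411), without chromosomes 2 and 13 (1929), without 27_6 replicate 2 (2972) and the second set alone (2182). It was 1662 at 10 CPM or more (9086 genes tested) and 1612 with 18_4 and 18_2 as separate lines (cause not tested). It was 1026 with a log2 size of at least 1 and 898 at adjusted p under 0.01, both by construction. The first set alone gave 350, where the cause was not tested. Leaving out lines gave 375 to 2734; the low counts are without a wild-type line (375 without 27C1, all shared with the 2525; 495 without 27C2, 493 shared), where the lone line is assumed to vary like the knockout lines.

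For the lines, no filter gave 764 for line 18 and 41 among knockout lines. DESeq2 gave 1139 (18), 2428 (27_6), 942 (27_7), 131 among knockout lines and 530 in all lines. The set block gave 1277 (18), 2052 (27_5), 2778 (27_6), 961 (27_7), 6 among knockout lines and 526 in all. The replicate block gave 526, 1209, 1605 and 470, with 3 among knockout lines and 258 in all. A log2 size of at least 1 gave 749 for 27_6. With 18_4 and 18_2 apart, these called 100 and 220, and 45 genes were called in all lines. Limma voom called 1 among knockout lines. Leaving out libraries gave 97 to 800 (18), 187 to 1502 (27_5), 156 to 3642 (27_6), 28 to 591 (27_7), 2 to 103 among knockout lines and 26 to 283 in all. The wild-type lines gave 0 throughout. The causes were not tested.

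Camera called 11 lists and 0 with an estimated correlation, where the few degrees of freedom weigh against a call (other causes not tested). Other settings called 8 to 13 and leaving out lines 10 to 12. Over 86 named genes and their alternatives, 1640 values kept direction and side of the threshold, 198 lost the call, 22 gained it and 3 reversed, none of which passed: GCM1 (-0.0598, first set), ELF5 (-0.10, second set) and PLAC8 (0.24, second set; cause not tested). Most losses were without 27C1 (54 genes), without 27C2 (47) and in the first set alone (52). Of list values, 124 kept their call and 19 lost it. Depth limits low genes such as ANKRD1, TGFBI and the PSG genes, at a few CPM or less.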

Other observations

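The genes in these first paragraphs were chosen after their values were seen. They were not drawn from a fixed list and stand for no class. The junction protein gene PVRL1 (nectin-1) rose from 55.3 to 121.3 CPM (log2 1.13, edgeR). P-cadherin (CDH3) fell from 24.7 to 6.56 CPM (log2 -1.91, SE 0.19, adjusted p = 0.000535). Cingulin (CGN), of tight junctions, fell from 52.6 to 17.9 CPM (-1.56), MARVELD3 from 34.9 to 11.4 CPM (-1.62) and PLEKHA7, of adherens junctions, from 60.8 to 21.6 CPM (-1.50). SHROOM3, which drives apical constriction, fell by 1.36 on the log2 scale. AJUBA, a LIM protein that binds LATS kinases, fell from 170 to 44.0 CPM (-1.95, SE 0.14, adjusted p = 0.000163). GRHL2, a transcription factor of epithelial cells, fell from 73.3 to 31.4 CPM (-1.22), and DNMT1, the maintenance DNA methyltransferase, from 349 to 186 CPM (-0.91, SE 0.10, adjusted p = 0.000829). The kidney injury molecule HAVCR1 (-1.98) and the cytokine receptor subunits IL6ST (-1.28) and CSF2RA (-0.71) fell too.

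Some genes were close to off in 1 genotype. The parathyroid hormone receptor PTH2R, on chromosome 2, stood at 3.82 to 10.6 CPM in knockout libraries and at 0 to 0.0885 CPM in wild-type libraries. SBSN (4.17 and 0.0596 CPM), the receptor kinase LTK (2.38 and 0.0784 CPM) and HAPLN3 (8.16 and 0.416 CPM) were higher in the knockout lines. PCDH17, on proximal chromosome 13, stood at 0 to 0.123 CPM in knockout and 5.97 to 6.89 CPM in wild-type libraries. ITM2A (0.0283 and 2.13 CPM), CNTN4 (0.140 and 5.58 CPM) and LAYN (0.344 and 11.7 CPM) were lower in the knockout lines. SLPI, a secreted protease inhibitor, had 0 counts in the 8 knockout libraries and 1.68 to 3.13 CPM in wild-type libraries.

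Single lines had shifts of their own along chromosomes, as medians of log2 differences from the wild-type libraries. In line 27_6, the first 20 Mb of chromosome 5 (46 genes) stood at 0.31 and 0.40 in the duplicates, and genes after 40 Mb (410 genes) at -0.34 and -0.53. The other knockout libraries stood at -0.05 to 0.03 and at -0.09 to 0.02. On chromosome 8 (345 genes), 27_7 replicate 2 stood at 0.33, its duplicate at -0.08 and the other knockout libraries at -0.17 to -0.07. Between library sets within lines, 878 genes were higher and 391 lower in the second set, among them SRSF5 (0.95), MIR17HG (1.69) and IGF2 (-1.43).

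Other divisions of the 6 lines were compared with the real one. The real division called 2525 genes and the highest of the others 0, so 1 of 15 divisions gave as many. With 15 divisions the share cannot fall under 0.05.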
